A study of Mus musculus with 2 samples.

How the data were processed

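Total RNA of mouse subcutaneous adipose tissue was measured on Illumina bead arrays, with 1 array for a pool of RNA from mice housed at 30 °C (thermoneutrality) and 1 array for a pool from mice housed at 6 °C. Each pool held the RNA of 3 to 4 mice. Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns with a DNase I digestion, checked on a Bioanalyser and converted to biotinylated cRNA with a MessageAmp kit for Illumina arrays.

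The values used were the intensity of each of 45281 probes on a linear scale, as deposited by the authors in the series' value table, whose columns carry the accession of each sample. The scanner software and the normalization method are not given in the sources used here. The sorted values of both columns differed by at most 0.288% of the value, which is the outcome of quantile normalization or an equivalent step, so the arrays had been set to 1 distribution before deposition. The lowest intensity was 99.6 on both arrays, so the values were taken as not background-subtracted, which the sources used here do not state. Both other tables, with 16 columns of per-sample values (8 in each), named their samples by letters that match no label, and these columns were not used here. They hold unnormalized signals, bead standard errors and detection p-values, so no bead-level error, detection call or alternative from unnormalized signals is given.

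The analysis fixed first, a background correction of the unnormalized signals by their detection p-values with a detection filter, was replaced, since it needs those columns. Background was instead corrected per array with the normexp method of limma 3.58.1 in R 4.3.3, with an offset of 50, followed by quantile normalization and log2. This was the fallback fixed before the data were examined for a table without detection p-values, and it was applied here to values the authors had already normalized. The fitted background was 105 intensity units on both arrays, with an SD of 1.10 in the warm pool and 1.09 in the cold pool. It lay below the 5th percentile of intensity (111.5), so it marks the low end of the readings and not a typical dim probe. Differences are log2 of cold over warm on this scale, and the offset shrinks the difference of dim probes. The steps were tested on simulated data with 45281 probes and a log2 noise SD of 0.1 that was assumed, not measured. Of the probes above the 75th percentile of mean intensity, 49 of 50 changed 2.83-fold and 49 of 50 changed 4-fold passed the 2-fold rule in the right direction. Between the median and the 75th percentile, 18 of 50 and 34 of 50 passed. Each set of 50 mixed rises and falls in equal numbers, counted together. From the same starting level the offset shrinks a fall more than a rise. These counts therefore do not give the recovery of either direction alone. The background of the simulation was assumed too, just below the lowest intensity for every probe and without noise. Since noise and background were assumed, this shows how the offset shrinks known changes under them and says nothing about the rate of false calls.

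With 1 array per temperature, the difference between the pools could not be tested against replicate spread, and no p-value and no standard deviation or standard error over replicates is given. Spreads and binomial intervals given here are over probes, which are not replicates. A probe was counted by a fixed rule of size, a difference of 2-fold or more (1 on the log2 scale), with no filter on dim probes in the main counts. The number of arrays limits the precision. The files and the gene table used here do not pair probe identifiers with genes: 0 lines of that table hold an Illumina identifier. Counts are therefore of probes, of which several can measure 1 gene. The 47 gene lists fixed before the data were examined, among them thermogenic, lipid metabolism, mitochondrial and cell type marker lists, could not be applied. The rule for named genes took the 12 largest differences each way. For want of gene names, only the 2 largest each way are given, by probe identifier. Alternatives were the deposited values without background correction, cyclic loess or median scaling in place of quantile normalization, an offset of 16, and filters on mean intensity.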

Results

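The series compared gene expression in the subcutaneous fat of mice kept in the cold with that of mice kept at thermoneutrality, the range of temperature in which a mouse needs no extra heat production. Subcutaneous fat is a white fat depot in which cold exposure can bring out heat-producing beige adipocytes. The data were 2 arrays of 45281 probes, 1 of a warm pool (30 °C) and 1 of a cold pool (6 °C), each of RNA combined from 3 to 4 mice. There was no replicate in either group, so none of the differences below has a replicate check. Pooling averages over mice, and the spread between mice was not measured.

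Both arrays had the same distribution of deposited intensities. The median was 131 on each, the 75th percentile was 260.5, the 99th percentile was 7108 and the highest probe read 39513. The brightest 1% of probes held 27.9% of the summed intensity. Because the arrays had been set to 1 distribution, a shift of all probes in 1 direction cannot be seen in these values.

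The log2 intensities had a Pearson correlation of 0.961 and a Spearman correlation of 0.922 across probes, which are not independent replicates. The log2 difference was under 0.5 for 85.2% of all probes, many of them near background, where the offset keeps differences small. Over the 13585 probes of the brightest deciles (8 to 10) of mean corrected log2 intensity, it was under 0.5 for 60.5%. Of these probes, 14.5% differed by 2-fold or more, and their Spearman correlation was 0.859. Of the 100 brightest probes on each array, 66 were shared, and of the 1000 brightest, 753 were shared.

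The cold pool differed from the warm pool by 2-fold or more at 2214 probes. The intensity was higher in the cold pool at 1245 of these, 2.75% of all probes, and lower at 969, or 2.14%. Larger differences were mostly toward higher intensity in the cold pool. At 4-fold or more, 267 probes were higher and 41 were lower, so that 86.7% of them were higher. At 8-fold or more, 78 probes were higher and 5 were lower, and at 16-fold or more, 36 were higher and 3 were lower. At 1.5-fold the counts were 2703 higher and 2762 lower, a balance that setting both arrays to 1 distribution may have helped to bring about. On the deposited values without background correction, 938 probes were at least 2-fold higher and 692 lower, and 183 were at least 4-fold higher and 30 lower. At 16-fold on these values, 23 were higher and 1 was lower. These are counts of probes past a size, not of changes shown to exceed the variation between mice.

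**Figure D1:**
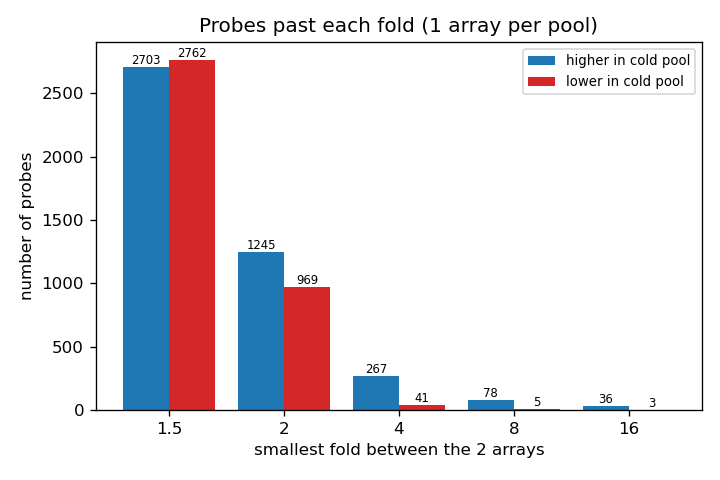
Number of probes (vertical axis) that differed between the pools by at least the fold on the horizontal axis, with blue bars for probes higher in the cold pool and red bars for probes lower in it. The bars are close at 1.5-fold (2703 and 2762) and far apart at 4-fold (267 and 41).

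The probe with the largest difference toward the cold pool was ILMN_2994373. Its deposited intensity was 181 in the warm pool and 17299 in the cold pool, which was 137-fold higher after background correction (7.10 on the log2 scale) and 95.5-fold higher as deposited. It was followed by ILMN_1236758, at 141 in the warm pool and 8015 in the cold pool, a log2 difference of 6.52, or 92.1-fold. Its warm-pool intensity was close to the array median. Its log2 difference was 5.82, or 56.7-fold, on the deposited values and 7.24 with an offset of 16. The size of its difference thus depends on the background correction and the offset. With that offset ILMN_2994373 was at 7.55. In the other direction, ILMN_2755578 read 4379.7 in the warm pool and 169.8 in the cold pool, a log2 difference of -5.24. ILMN_1241001 read 1801 in the warm pool and 113 in the cold pool. Its cold-pool intensity lay between the 5th percentile (111) and the 25th percentile (118) of the array, near the fitted background of 105, so the size of its difference is not determined. The computed log2 difference was -4.90 after background correction and -3.99 on the deposited values, and with an offset of 16 it was -6.14, beyond the -5.73 of ILMN_2755578, so the order of these probes depends on the offset.

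At 2-fold, the median intensity on the brighter array was similar in either direction, 859.8 in the cold pool for the 1245 higher probes and 965 in the warm pool for the 969 lower probes. At 4-fold the levels lay further apart. The 267 probes at least 4-fold higher in the cold pool had a median deposited intensity of 173 in the warm pool (quartiles 129 and 359) and 1154 in the cold pool (quartiles 585 and 2362). In the warm pool, 72 of them lay below the median of the array, and 180 lay too close to the floor to have been 4-fold lower. The floor is the lowest corrected value, 50.2 in each pool, and the chosen offset makes up nearly all of it. A probe 4-fold above it had a deposited warm-pool intensity of at least 255.84. The count of 180 therefore depends on the offset, and it was not repeated with a smaller one. Among the probes with a warm-pool value at least 4-fold above this floor, 87 were at least 4-fold higher and 41 lower. All 41 lower probes pass this filter by construction, so it could only remove higher probes. The 41 probes at least 4-fold lower had a median of 3727 in the warm pool (quartiles 1801 and 6596) and 748 in the cold pool (quartiles 301 and 1439), and 3 of them lay below the array median in the cold pool. At 2-fold, 178 of the 1245 higher probes and 16 of the 969 lower probes were below the array median on their dim side.

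Differences of 2-fold or more were all among probes in deciles 6 to 10 of mean corrected log2 intensity, decile 10 being the brightest. In decile 1, the spread of log2 differences (a standard deviation scaled from the median absolute deviation over probes) was 0.118. It was 0.513 in decile 8 and 0.614 in decile 10. This spread is over probes of 1 pair of arrays and holds both measurement error and differences between the pools. It is narrowed in dim probes by the background and the offset. In decile 10, with a median intensity of 1806, 397 probes were at least 2-fold higher in the cold pool and 383 were lower. In decile 8, with a median intensity of 266, the counts were 307 and 248. In decile 7, with a median of 169, they were 171 and 48.

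**Figure D2:**
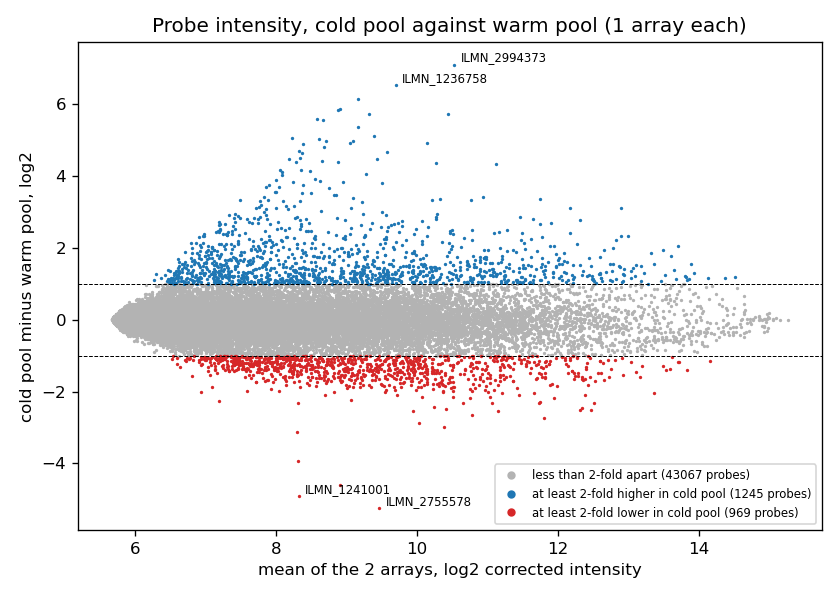
Difference between the cold and the warm pool for each probe (vertical axis, log2) against its mean corrected intensity on both arrays (horizontal axis, log2), with dashed lines at a 2-fold difference. Blue points are the 1245 probes at least 2-fold higher in the cold pool, red points the 969 lower, and the probes with the largest differences are labelled.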

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

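The 2-fold counts stayed within 1.5 times of 1245 higher and 969 lower under the alternatives that were run, except that an offset of 16 in place of 50 gave 1457 lower probes, just over 1.5 times the main count. They ranged from 938 to 1702 for higher probes and from 692 to 1457 for lower probes, and higher probes made up 53.7% to 61.8% of them. The 4-fold counts, a result added after seeing the data, also moved with that offset: 409 probes were higher (267 in the main values) and 67 were lower (41), since a smaller offset shrinks dim probes less. The share of higher probes among them was then 85.9%. Running an offset of 16 on these values and the filters on mean intensity were chosen after seeing the data. However, 16 was the offset of the analysis fixed first, and 50 that of its fallback. The filter at the median removed none of the probes counted, which says nothing about stability, since with an offset of 50 so dim a probe can hardly reach 2-fold. The 4 named probes kept their direction under every alternative run, but with an offset of 16 ILMN_1241001, whose cold-pool reading is near background, went from -4.90 to -6.14 and ranked before ILMN_2755578 at -5.73. Alternatives fixed before the data were examined that need detection p-values or unnormalized signals, and the mean over the probes of a gene, were not run, and the alternative of no detection filter is the main setting. No replicate could be left out, and no paired analysis was possible because each temperature had 1 array.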

Other observations

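The pattern described here was chosen after the counts were seen. The bounds of the loess test were set before its result was seen, and the filter on the warm-pool level was chosen afterwards. Of the probes at least 4-fold apart, 86.7% were higher in the cold pool, while at 1.5-fold the counts in either direction were close. Because both arrays had been set to 1 distribution, many small falls can offset a few large rises. The balance at 1.5-fold may therefore be partly imposed. Median log2 differences were slightly negative in each of deciles 7 to 10, from -0.038 to -0.058. A brightness-dependent trend of the bulk of probes, left after normalization, is argued against as the whole cause. After cyclic loess, 290 probes were higher and 33 lower, or 89.8% (95% exact binomial interval 86.0 to 92.9, which treats probes as independent). There was little such trend to remove, with a median log2 difference of -0.058 in decile 8 and -0.048 in decile 10. The loess test therefore adds little to these medians. Both follow the bulk of probes, and setting the arrays to 1 distribution tends to keep such medians small. They say nothing about a trend removed before deposition or one limited to the few probes far apart. Less room above background for probes to be lower stays open. In the warm pool, 180 of the 267 higher probes lay too low to be 4-fold lower, a count that depends on the chosen offset. Among probes whose warm-pool value was at least 4-fold above the floor, 87 were higher and 41 lower, or 68.0% (59.1 to 75.9). All 41 lower probes pass this filter by construction, so the share could only fall. The filter therefore cannot decide the question, and nothing is concluded from its share. An earlier test took probes whose brighter array read over 1000, which treats both arrays alike. Compared with its brighter reading, each such probe had room to be 4-fold dimmer on the other array. That is not the same as room to fall 4-fold from its warm-pool value. The test gave 140 higher and 35 lower, or 80.0% (73.3 to 85.7), so the excess of higher probes also held there. The test still holds probes that lay near background in the warm pool and, in mirror, probes that lay near background in the cold pool. It thus does not single out probes with room to fall 4-fold from the warm-pool value. Lack of room therefore stays open as a part of the cause. Other explanations were not tested, and those given here are not a full list. Housing temperature may have raised a set of genes from low levels, or 1 mouse of a pool could have supplied them. The pools could also have differed in tissue carried along at dissection. Any difference in the handling of the arrays also went with temperature. With 1 pool per temperature and no gene names for the probes, the values used here hold nothing that separates these.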
